A study of Homo sapiens with 4 samples.

How the data were processed

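A-498, an established human cell line from a kidney carcinoma, was used in a CRISPR interference (CRISPRi) screen, in which guide RNAs direct the catalytically dead Cas9 protein (dCas9) to a target so that its transcription is blocked. Per the labels, 2 independent clones of dCas9-expressing A-498 cells (clones 2 and 4) carried the guides, cells were selected with puromycin, and genomic DNA was taken at day 0 and after prolonged growth at day 19. The guide cassettes were amplified from genomic DNA by 2 rounds of PCR and sequenced. The 4 libraries form the groups day 0 and day 19, each with 1 library of clone 2 and 1 of clone 4.

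The deposited values were guide reads per 1000000 reads of the library (CPM) plus 1, computed by the authors. Each column of the deposited table summed to 1000000 plus its number of guides, 1012468 in all, and its smallest value was 1. After subtraction of 1, every value was a whole multiple of the worth of 1 read, within 0.01 reads. That step was 0.127 CPM in clone 2 at day 0, 0.0973 in clone 2 at day 19, 0.0957 in clone 4 at day 0 and 0.109 in clone 4 at day 19. It gave totals of 7886412, 10282496, 10448387 and 9173409 guide reads in the same order. Read sampling alone gave an SD of 0.08 for the log2 change of a control guide in clone 2 and 0.07 in clone 4. A guide at 0 in clone 2 at day 19 had an upper limit of 0.292 CPM (3 reads of that library). Such limits cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The submitters' processing notes name bcl2fastq, MAGeCK and GRCh38 with no version of the tools. How reads were assigned to guides is not given in the sources used here.

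The table held 12468 guides in 800 gene entries and 1 entry of 450 negative control guides. A guide was kept if its mean over the 4 libraries reached 10% of the median guide's mean, a cutoff of 7.44 on the deposited scale. This kept 11748 guides, with all 450 control guides, and left out 720, of which 692 were at 0 in all 4 libraries. Entries with at least 3 kept guides were tested (765), and 35 were not. Guide sequences and target positions were not used here. Of the 800 entries, 144 matched a RefSeq gene (GRCh38.p14) by symbol and 30 by an older name, and 626 had no match. Coordinates are those of the matched RefSeq genes, since GRCh38 is also the build in the submitters' notes.

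Guides were compared between the days with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on log2(deposited value + 5), with day as the factor, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. A log2 change on this scale understates the change of low guides. Entries were tested by robust rank aggregation (RRA) of their guides, ranked by limma's moderated statistic, in its alpha form with alpha 0.25. This gene test of MAGeCK was written anew in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Its one-sided permutation p came from 100000 random draws of as many guides, so that 1e-05 was the smallest p it could give. A called entry had an adjusted p under 0.05 and a median guide change of the called sign in both clones. The sign was taken on the deposited scale, not relative to control guides. The RRA p measures agreement among an entry's guides against the library and leaves out the spread between clones. Plots were drawn with matplotlib 3.10.9.

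The change of an entry is the median log2 change of its guides, day 19 over day 0, in each clone. Against day 0, control guides lay at −0.59 in clone 2 and −0.19 in clone 4 on the deposited scale. Changes are therefore given relative to the median control guide of the same clone, as the mean of both clones ± SD over 2 clones, unless the deposited scale is named. The median change over all entries was −0.34 as deposited, 0.05 with each library centred on its control guides and 0.01 with median-of-ratios size factors.

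The clone number pairs the libraries, because the same clonal line was sampled at both days. Over guides, the deviations of the clones from the group means at day 0 and day 19 correlated with r = 0.63. No source states a paired test, so the fit without a clone block was the main one. The libraries of the 2 clones were not copies of each other, with a chi-square per guide of 25.0 at day 0 and 363 at day 19. With 2 libraries a side, an exact permutation test of a single value cannot go below p = 0.33, so none was printed. The p-values from limma measure the spread between these clones of 1 cell line.

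Gene lists were tested with limma's camera (preset correlation 0.01, with an estimated correlation as alternative) on the mean log2 value over an entry's guides, where a list had 5 or more tested entries. Other lists were given as counts. The 17 lists held ribosomal proteins, proteasome, core splicing, RNA polymerases, DNA replication, ribosome biogenesis factors, clear cell renal and hypoxia genes, growth restraining genes, CRNDE and its neighbours, snoRNA host lncRNAs, microRNA host lncRNAs, housekeeping noncoding RNAs, lncRNAs much studied in cancer, antisense-named, divergent-named and intergenic-named lncRNAs, and lncRNAs named for a core gene. The difference between the clones was tested per entry by flipping the sign of each guide's clone 4 minus clone 2 change. This was exact up to 14 guides and used 100000 random flips above that.

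The rule for named entries took the 14 depleted entries with the lowest mean change and the 8 enriched entries with the highest. It added CRNDE and, from each list, up to 3 called members with the largest change, or the member with the smallest unadjusted p where none was called. The values of 1 entry that the rule names are not reported here, and it is left out of the plots of single entries, while counts, lists and correlations include it. The lists, this rule, the tests and most other settings tried were fixed before the data were examined. These settings changed the filter, pseudocount, scaling, clone block, ranking, alpha, null, sign requirement and threshold, left out each library in turn, used each clone alone, and replaced RRA by limma on entry means or by random draws of guides. Count models were not run on the recovered reads.

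The steps were tested on simulated data with the depth and control guide spread of these libraries, in which 200 of 765 entries were changed through 70% of their guides. For the comparison of day 19 with day 0, 47.5% of the 80 entries with a simulated log2 change of −1 were called, as were 90% of the 40 entries at −2 and 66.2% of the 80 entries at 1. No unchanged entry was called (0 of 565). Far more entries were changed there than the 11 of 765 called in the data, which eases the Benjamini-Hochberg threshold. The shares called may therefore overstate what was found at these sizes in the screen itself. Day 0 differences between the clones were simulated with an assumed spread, and the later changes were drawn independently of them. In the data, the day 0 ratio of the clones correlated with the clone 2 change over control guides (r = 0.45). The shares called and the 0 false calls hold for the simulated noise only.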

Results

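The abundance of CRISPRi guides in A-498 cells was measured at day 0 and day 19 in clones 2 and 4, with 2 libraries per day. Library depth was 7886412 guide reads for clone 2 at day 0, 10282496 for clone 2 at day 19, 10448387 for clone 4 at day 0 and 9173409 for clone 4 at day 19. The median kept guide had 627, 526, 843 and 684 reads in the same order. Most entries (585 of 800, or 73.1%) had 10 guides, and 204 had 20 or more. Of the entries matched to RefSeq, 143 were lncRNA genes and 22 protein-coding genes.

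The comparison of day 19 with day 0 asks which targets, when silenced, cost or favoured growth of A-498 cells. Guides against ribosomal protein genes, which encode structural parts of the ribosome, were lost most. RPS18 guides had a log2 change of −1.87 ± 0.12 relative to control guides (SD, n = 2 clones). RPL6 stood at −1.66 ± 0.24 and RPS19 at −1.61 ± 0.26. These sizes depend on the 5 added before the log2 was taken. On the deposited scale RPS18 changed by −2.26, and by −3.09 with pseudocount 1 and −1.27 with pseudocount 20. Of 765 entries, 11 were depleted (RRA, adjusted p under 0.05), and 10 of these were ribosomal protein or DNA replication genes. Limma on entry means, without pairing the libraries of a clone, called 0 entries lower on the deposited scale, with 49 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.0608. It called 3 lower with the libraries centred on control guides, all among the 11. With the clone as a block it called 15 lower on the deposited scale and 14 centred on control guides, with all 11 in both. The blocked fits had 1 residual degree of freedom and gave every entry the same SE (0.261 and 0.17). Their further entries were RPL8, PXN-AS1 and XXbac-BPG252P9.9, and RP11-486O12.2 on the deposited scale, named after their values were seen.

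Of the 9 ribosomal protein genes in the library, 8 were depleted, among them RPL7A at −1.40 ± 0.14, RPL32 at −1.30 ± 0.98, RPS15A at −1.28 ± 0.61 and RPS21 at −0.39 ± 0.16. RPL8 was not called by RRA (−0.41 ± 0.45, RRA permutation p = 0.00786, adjusted p = 0.376). All 9 passed when adjusted over the list alone. RPL8 had the largest p of the 9, so that adjustment left its p unchanged and adds no support to it. The median guide of RPS18 went from a deposited value of 47.2 to 1.88 in clone 2 and from 52.9 to 8.90 in clone 4. All 10 guides of RPS18 lay below the control median in both clones, compared with 24.7% of control guides. In GRCh38, RPS18 lies on chromosome 6 (33272075 to 33276511). RPS18, RPL6, RPS19, RPL7A and RPS15A reached the smallest p the random draws could give (1e-05, RRA adjusted p = 0.000956). RPL32 had an RRA adjusted p of 0.0034 and RPS21 of 0.0299. As a list, ribosomal proteins were lower at day 19 (limma's camera, adjusted p = 9.01e-18 with the preset correlation). The adjusted p was 0.408 with an estimated correlation, so that the list test did not hold there. On the deposited scale RPL32 changed by −1.69, by −0.55 without the day 19 library of clone 2 and by −2.60 without that of clone 4. The calls of RPL32 and RPS21 were lost without the filter on low guides, and that of RPL7A without the day 19 library of clone 4.

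Of the 3 replication genes, 2 were depleted. RPA1, the large subunit of the single-strand DNA binding complex, fell by 1.07 on the log2 scale (SD 0.20 over 2 clones), and PCNA, the sliding clamp of the replication fork, by 0.71 (SD 0.12). Both had an RRA adjusted p of 0.000956. RPA3, the small subunit of the RPA1 complex, had a mean change of −0.47 ± 0.18 and was not called over all entries (RRA permutation p = 0.0179, adjusted p = 0.628). All 3 replication genes passed when adjusted over the list alone. RPA3 had the largest p of the 3, so that adjustment left its p unchanged and adds no support to it. The call of PCNA was lost without the filter on low guides. Its deposited-scale change was −1.10, and −0.60 without the day 0 library of clone 4 and −1.70 without the day 19 library of clone 4.

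KB-1043D8.6, an entry named after a genomic clone and without a match in RefSeq, was the remaining depleted entry. Its guides fell by 1.12 on the log2 scale, with an SD of 0.02 over the 2 clones. This SD does not measure precision. Medians of random sets of 10 control guides varied with an SD of 0.38 in clone 2 and 0.21 in clone 4. The RRA adjusted p of KB-1043D8.6 was 0.0298, and 6 of its 10 guides lay below the control median in both clones. The median guide went from 71.0 to 22.2 in clone 2 and from 89.4 to 41.6 in clone 4, as deposited. The call was lost without the day 19 library of clone 4, in clone 2 alone (adjusted p = 0.0789), with pseudocount 1 and without the filter on low guides. It was also lost when any of 3 of its 10 guides was left out (RRA adjusted p up to 0.209).

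**Figure D1:**
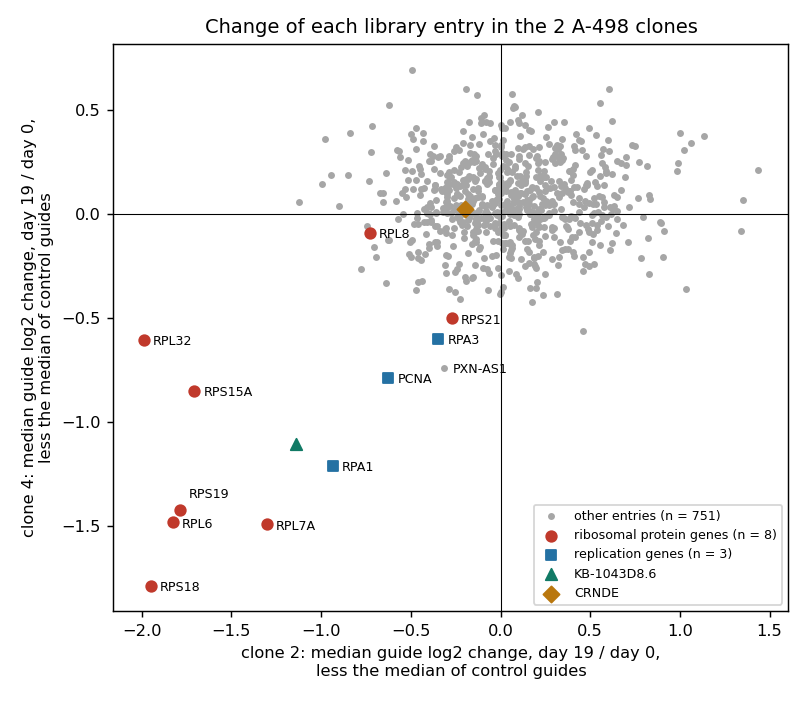
Each point is a tested entry, with its median guide log2 change (day 19 over day 0, less the median control guide) in clone 2 on the x axis and in clone 4 on the y axis. The ribosomal protein genes shown, the replication genes and KB-1043D8.6 lie below 0 on both axes, RPS18 at −1.95 and −1.79, while CRNDE lies at −0.20 and 0.03.

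No entry was enriched at day 19 (RRA, 0 of 765). At an unadjusted p under 0.05, 48 entries passed in that direction, and the smallest adjusted p was 0.309. RP11-580I16.2, which had that adjusted p and stood at 0.54 ± 0.12 over 20 guides, was enriched when the clone was a block in the fit (1 entry) and when guides were ranked by their mean change. It is named here after its values were seen. Limma on entry means called 0 too, with 0 higher at an unadjusted p under 0.05 on the deposited scale, where control guides fell, and 20 when centred on control guides. With the clone as a block it called 0 on the deposited scale and 4 when centred (55 at an unadjusted p under 0.05), namely CTD-2653D5.1, RP11-261P9.4, RP5-1063M23.1 and RP5-884C9.2, which are named after their values were seen.

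CRNDE, the lncRNA named in the title of the series, was targeted by 40 guides and was not called. Its median guide changed by −0.20 in clone 2 and 0.03 in clone 4 relative to control guides, a mean of −0.09 ± 0.16 (SD, n = 2 clones). The RRA depletion p, from random draws, was 0.283 (adjusted p = 1), and 10 of the 40 guides lay below the control median in both clones. As deposited, the median CRNDE guide was 80.5 at day 0 and 48.5 at day 19 in clone 2, and 79.8 and 71.4 in clone 4. In GRCh38 the gene lies on chromosome 16 (54918863 to 54928886), and its neighbours IRX5 and IRX3 were not among the entries.

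The lists of noncoding RNAs held no called entry. Of the snoRNA host lncRNAs 0 of 6 tested were called, of the lncRNAs much studied in cancer 0 of 12, of the antisense-named lncRNAs 0 of 73 and of the intergenic-named lncRNAs 0 of 39 (camera adjusted p = 0.937 for each of these 4 lists, and 0.978 with an estimated correlation). Among these, SNHG7 stood at 0.15 ± 0.05, TUG1 at 0.11 ± 0.11 and LINC00460 at 0.04 ± 0.24, which were −0.24, −0.28 and −0.35 on the deposited scale. Camera, which sets a list against the other entries, put snoRNA hosts up although their median was −0.05, and antisense-named lncRNAs down although theirs was 0.04. PXN-AS1, antisense to the gene of the focal adhesion protein paxillin, stood at −0.53 ± 0.30 and had an RRA adjusted p of 0.120. Its change was −0.32 in clone 2 and −0.74 in clone 4, and it was not called in either clone alone. It was called depleted without the day 19 library of clone 2, against random draws of guides and by limma on entry means with the clone block.

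In the smaller lists, 0 of 4 clear cell renal and hypoxia genes were called, with the hypoxia-induced microRNA host MIR210HG at −0.10 ± 0.03, and 0 of 3 lncRNAs named for a core gene, with MCM3AP-AS1 at −0.23 ± 0.01. The list of growth restraining genes held CDKN2B-AS1, at 0.00 ± 0.06, and that of housekeeping noncoding RNAs held RNU12, at −0.18 ± 0.38, an RNA of the minor spliceosome. Neither was called. Among 3 microRNA host lncRNAs 0 were called over all entries, and 1 passed when adjusted over the list alone. This was MIR4435-1HG (RRA permutation p = 0.00994 over 73 guides), which is named after its values were seen. Its change was −0.04 ± 0.15, with 0.07 in clone 2 and −0.15 in clone 4. It thus lay above control guides in clone 2 and met the sign rule only on the deposited scale (−0.53 and −0.34). For every other noncoding list, 0 entries passed when adjusted over the list alone. The lists of proteasome, core splicing, RNA polymerase and ribosome biogenesis genes and of divergent-named lncRNAs had 0 entries.

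**Figure D2:**
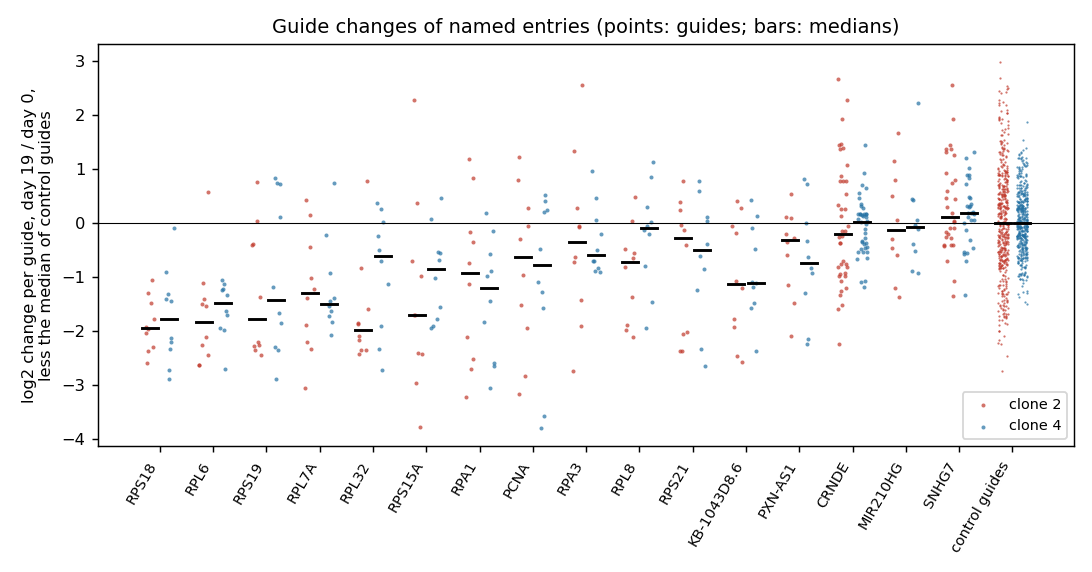
Each point is 1 guide, with its log2 change (day 19 over day 0, less the median control guide) on the y axis, clone 2 in red and clone 4 in blue. Bars are medians over the guides of an entry, which lie at −1.95 and −1.79 for RPS18, at −1.14 and −1.10 for KB-1043D8.6 and at −0.20 and 0.03 for CRNDE.

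Guide by guide, 0 of 11748 guides passed in either direction on the deposited scale (limma, adjusted p under 0.05). At an unadjusted p under 0.05, 478 were lower and 36 higher at day 19, control guides included with 19 and 1. These counts depend on the scaling, with 232 lower and 187 higher when centred on control guides, and 258 and 152 with median-of-ratios size factors. With the clone as a block, 55 guides were lower and 0 higher on the deposited scale, and 20 and 0 when centred on control guides. On the deposited scale without the day 19 library of clone 2 the counts were 1576 lower and 732 higher, and without that of clone 4 they were 5645 and 1676. In these fits the spread came from the day 0 pair alone, and the lone day 19 library is assumed to vary like it.

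All 11 depleted entries were lower than control guides in both clones. They were picked as low over both clones together, so this is no independent check. The rule that a call needs a negative median change in both clones was applied on the deposited scale. Control guides themselves lay at −0.59 in clone 2 and −0.19 in clone 4 there, so the rule asks little of a depleted entry. It removed none, since the same 11 were called without it. Over the 12 ribosomal protein and replication genes, the changes in clone 2 and clone 4 correlated with Pearson's r = 0.642 (Spearman's rho = 0.685), and over the other 753 entries with r = 0.0457 (rho = 0.0231). Over all 765 entries r was 0.288 (rho = 0.0642), and over 11748 guides it was 0.0836 (rho = 0.0515), close to 0.0565 over the control guides. These correlations are across genes or guides, which are not independent replicates.

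RPL32 guides changed by −1.99 in clone 2 and −0.61 in clone 4, and RPS15A guides by −1.71 and −0.85. As deposited, 9 of 765 entries changed differently in the clones (sign-flip permutation, adjusted p under 0.05), all 9 higher in clone 4, as SNHG12 with 60 guides (−0.76 in clone 2 and −0.10 in clone 4 as deposited). All 9 had 30 or more guides, which follows in part from the test. With 10 guides, as in each depleted entry, the smallest exact p was 0.00195, which adjusted to 0.0786, so that no depleted entry was able to pass. After each clone was centred on its control guides, 0 entries differed, with 25 at an unadjusted p under 0.05 and a smallest adjusted p of 0.747. For RPL32 the exact p of the centred difference was 0.0508 (adjusted p = 0.976). With 1 library per clone and day, the test compares these libraries and not clones in general.

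**Figure D3:**
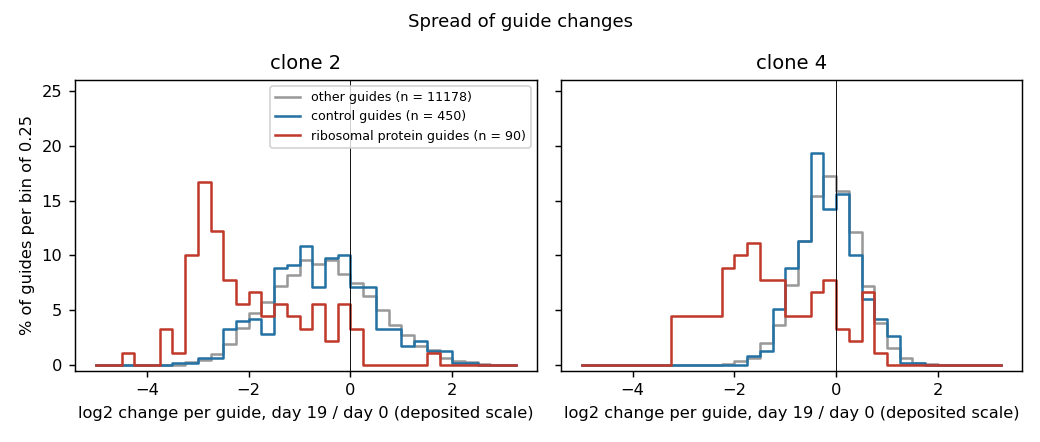
The x axis is the log2 change per guide on the deposited scale and the y axis the percent of guides in each bin, for clone 2 (left) and clone 4 (right). Control guides spread with an SD of 1.02 in clone 2 and 0.58 in clone 4, and ribosomal protein guides peak to the left of them in both.

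Guides were less evenly represented at day 19 than at day 0, as seen in 1 library per clone and day. The Gini coefficient of kept guides went from 0.218 at day 0 to 0.531 at day 19 in clone 2, and from 0.202 to 0.319 in clone 4. The top 1% of guides held 9.89% of the total in clone 2 at day 19, against 2.79% at day 0, and 3.53% against 2.53% in clone 4. Of the kept guides, 20 were at 0 in clone 2 at day 19, and 1 in clone 4 at day 19. The log2 changes of control guides had an SD of 1.02 in clone 2 and 0.58 in clone 4, near those of all guides, 1.03 and 0.61.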

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

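Apart from the test of the clones on the deposited scale, the tests of this part were chosen after the result was seen. On the deposited scale, 9 entries changed differently in the libraries of clone 2 and clone 4 by sign flips over guides. With 1 library per clone and day, this compares libraries and does not show a difference between the clones. SNHG12, LAMTOR5-AS1, PCBP1-AS1, LINC00240 and LINC00969 were among the 9. Over all guides, the median of the clone 4 change less the clone 2 change was 0.43. After each clone was centred on its control guides, the count was 0. Entries of 10 guides were not able to pass this test on the deposited scale (smallest adjusted p 0.0786).

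The pattern weighed here is the wider spread of guide changes in clone 2 (SD of control guides 1.02, against 0.58 in clone 4), with little agreement between the clones outside ribosomal protein and replication genes. Read sampling accounts for 0.651% of the control guide variance in clone 2, and control guides spread nearly as widely as all guides (ratio of SDs 0.991), so neither sequencing depth nor effects of the guides on their targets give this spread. Noise that arose only in making the day 19 library would leave no trace at day 0, yet over 450 control guides the day 0 log2 ratio of clone 2 to clone 4 correlated with the later clone 2 change (r = 0.45, lower 95% bound 0.371, permutation p = 0.0001, the smallest the permutations can give), and with r = −0.03 with the clone 4 change. This argues against such noise as the only source, and leaves open how much of the spread arose after day 0. A candidate explanation for the part seen at day 0 is unequal growth of cells already under way in clone 2. Guides carried by faster cells would then have risen whatever they targeted. Day 19 reads mixed into the day 0 library of clone 2 would give the same sign (slope 0.144 CPM per CPM). Such mixing cannot be told apart from unequal growth, because both predict a day 0 level shifted towards the day 19 level. Other biological differences of the clones were not tested.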

How the results depend on the processing

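Alternatives added after the data were seen were clones scaled to the spread of control guides, clones centred on control guides, blocks of 10 guides, the clone block centred on control guides, and limma on entry means with the clone block, centred on control guides or both. The planned count-model tests (edgeR and DESeq2) were not run. For the depleted entries, some alternatives could hardly lose a call. The adjusted p threshold of 0.25 and the setting without a sign requirement contain the main calls, and scaling to equal totals barely changes the values. Each depleted entry was already 1 block of 10 guides. Of 29 alternatives, 20 called all 11, these among them. The count was 7 without the filter (RPL32, PCNA, RPS21 and KB-1043D8.6 lost), 0 with limma on entry means (3 centred on control guides, 15 with the clone block, 14 with both), 10 to 12 when each library was left out in turn, and 11 with blocks of 10 guides. RPL7A and KB-1043D8.6 were lost without the day 19 library of clone 4. RPL32 was also lost with the 30% filter, RPS21 with pseudocount 1 and in clone 4 alone. Enriched entries numbered 1 with the clone block, centred or not, 4 with limma on entry means blocked and centred, 1 when ranked by mean change, and 0 with any library left out. In the guide fit, the clone block, which pairs the libraries, gave 12 depleted entries and 55 depleted guides (20 centred on control guides), and changed no other RRA call than those of XXbac-BPG252P9.9 and RP11-580I16.2. Leaving out a library gave 0 to 5645 depleted and 0 to 1676 enriched guides. Agreement of the clones was 0.103 over guides and 0.358 over entries with pseudocount 1, and 0.203 over entries with pseudocount 20. Entries differing between clones fell from 9 to 0 after centring. That fall followed removal of the offset between the control guides of the clones (−0.59 in clone 2 and −0.19 in clone 4). Entries at an unadjusted sign-flip p under 0.05 went from 174 to 25. The cause of the other moves was not tested, except that fits without a day 19 library take their spread from the day 0 pair.

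The ribosomal protein list was called in 8 of 9 alternatives and not with an estimated correlation (adjusted p = 0.408). List directions turned, with no call, for antisense-named lncRNAs (adjusted p = 0.995 with the clone block, 0.945 centred on control guides), for lncRNAs much studied in cancer (0.995 and 0.945) and for snoRNA hosts (0.995 with the block). With libraries left out, the adjusted p ranged from 0.787 to 0.998 for the first 2 lists and from 0.685 to 0.998 for snoRNA hosts. Deposited-scale changes of uncalled entries turned positive with median-of-ratios, control centring and control scaling: SNHG7 (0.12, 0.14, 0.15), TUG1 (0.081, 0.11, 0.113) and LINC00460 (0.00804, 0.0375, 0.0405). With libraries left out, SNHG7 ranged from −0.506 to 0.0397 and RNU12 from −1.08 to 0.055, the highest without the day 19 library of clone 2. Over all named entries and alternatives, direction and call held in 466 cases, a call ended in 30, began in 4 and a direction turned in 20. Depth gave a median of 526 or more reads per guide, and read sampling made up 0.651% and 1.56% of the control guide variance in clones 2 and 4.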

Other observations

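All tests of this part except that on neighbouring genes were chosen after results were seen. Outside the ribosomal protein and replication lists, the entries lay close to the control guides. The 537 entries of 10 guides had mean changes with an SD of 0.23, and 10000 random sets of 10 control guides had an SD of 0.22. Below the 2.5th percentile of the control sets (−0.41) lay 10 of these entries (1.86%), and above the 97.5th percentile (0.44) lay 25 (4.66%). Single lncRNAs known for abundance stood near control guides, as MALAT1 at −0.21 ± 0.25 and NEAT1 at −0.15 ± 0.21.

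Of the entries, 34 were listed at 0 with every guide in all 4 libraries, 630 guides in all. They include LINC00649 with 100 guides, SBF2-AS1 with 30 and the snoRNA host SNHG3 with 10. In 8 more entries, 62 guides were at 0 throughout, LINC00152 among these entries. These values belong to no comparison, since nothing was measured at day 0.

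KB-1043D8.6 was the only depleted entry outside the ribosomal protein and replication lists. The arithmetic mean of its guide changes over both clones was −0.97, and between −1.09 and −0.84 with 1 guide left out in turn, below the lowest such mean of 10000 random sets of 9 control guides (−0.65), which argues against 1 guide as the source of the loss. The unadjusted RRA permutation p then reached 0.00355 at most, while the adjusted p ranged from 0.0145 to 0.209 and the call was lost for 3 of the 10 guides. The entry was called in clone 4 alone, and clone 2, which did not enter that call, gave an RRA permutation p of 0.00134. Adjustment over the 10 entries called in clone 4 alone left this p unchanged. The other 9 were ribosomal protein or replication genes with smaller p in clone 2, so that adjustment corrects nothing. The unadjusted p argues against 1 clone as the only source, but the entry was first picked by a call that used both clones. Over all entries the adjusted p in clone 2 alone was 0.0789, although the change was as large there (−1.14, and −1.10 in clone 4). Silencing of a neighbouring gene and off-target binding stay open and untested, as does a growth effect of the transcript itself.

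It was hypothesised that CRNDE was not called because its 40 guides pool separate target sites. Taken as blocks of 10 consecutive guides, which is an assumed order of sites, the 4 blocks had a lowest adjusted RRA p of 1 over 1085 blocks. The lowest block stood at −0.48 (RRA permutation p = 0.222), below the 2.5th percentile of the control sets. That percentile makes no allowance for taking the lowest of 4 blocks, and the other blocks stood at −0.23, −0.11 and 0.09. How large an effect the test would find in 40 guides or in 1 block was not simulated, and pooling stays open.

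A second hypothesis was that loss of guides against ribosomal protein and replication genes had begun by day 0. Over their 120 guides, the day 0 level in clone 4 correlated with the later change in clone 2 (Spearman's rho = 0.273, Pearson's r = 0.245, permutation p = 0.0033, adjusted p = 0.00495 over 3 tests). The day 0 level in clone 2 correlated with the later change in clone 4 (rho = 0.372, r = 0.307, p = 0.0001, the smallest the permutations can give, adjusted p = 0.0003). Control guides gave rho = 0.0888 (permutation p = 0.0555) and 0.0196 (permutation p = 0.679). At day 0 the median of the 120 guides was 73.3 in clone 2 and 70.4 in clone 4, and that of control guides 79.9 and 80.9, as deposited. The permutations over all 120 guides treated them as independent, although they belong to 12 genes, so their p-values are too small. Within genes, r was 0.151 (permutation p = 0.121) and 0.271 (permutation p = 0.0080). The first relation was thus not past 0.05 inside genes. The second relation uses the day 0 library of clone 2, and day 19 reads mixed into that library would give the same sign. Such mixing was not excluded. An early start of the loss is thus 1 possible reading of the values, and an uneven make-up of the guide library itself was not tested.

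The third hypothesis was that lncRNA entries within 1 kb of a protein-coding gene are lower because the neighbour is silenced. The 82 such entries had a mean change of 0.03 and the other 53 had 0.09, a difference of −0.07 (permutation p = 0.0458, adjusted p = 0.0458 over 3 tests). Without PXN-AS1, the lowest of them, the difference was −0.06 (permutation p = 0.0635). Coordinates were at hand for 17.9% of the 753 entries only, so the test does not speak for the rest. Among the entries with coordinates the difference was small, both means lay above control guides, and the permutation p was under 0.05 only with PXN-AS1. The test therefore does not decide whether neighbours were silenced.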
